A study of Mus musculus with 24 samples.

How the data were processed

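Ribosome-protected fragments (RPFs, the stretches of mRNA shielded by translating ribosomes) and total RNA were sequenced from bone-marrow-derived macrophages of wild-type (WT) and Apobec1-deficient (KO) mice. Per the labels' protocols, marrow precursors from C57BL/6 mice aged 6 to 12 weeks were cultured for 7 days in 20 ng/mL M-CSF, the growth factor that drives macrophage differentiation, and the RNA and RPF libraries were made with a commercial ribosome profiling kit. The labels give 6 KO and 6 WT cultures, each with 1 RPF and 1 total RNA library (24 libraries), and place them in 3 batches. Batch 1 held KO1 and WT1 to WT3, batch 2 held KO2 to KO4 and WT4, and batch 3 held KO5, KO6, WT5 and WT6. The labels do not state that each culture came from its own animal, so p-values measure only the spread between these samples, which may be technical.

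The deposited values of each library were whole-number read counts per gene symbol, not normalized. The deposited RPF counts were limited to coding sequence per the file names, while the total RNA counts were marked as strict with no stated region; because the counted regions may differ, a footprint to RNA ratio is comparable between cultures for a gene and less so between genes. The RPF tables listed only genes with at least 1 count, and absent genes were taken as 0. Trim Galore, Bowtie 1.1.2, TopHat2 2.1.0, HTSeq, Cufflinks 2.2.1, DESeq and DESeq2 and the mouse build mm10 were named per the submitters' processing notes, with no role or order. Strandedness, the annotation release and the handling of reads with several alignments were not given in the sources used here. The 5 HTSeq summary lines of each file were kept out of library sizes and tests. Reads without a single alignment made up 27.8% to 51.2% of reads in total RNA files and 45.6% to 80.1% in RPF files, and reads outside any counted feature averaged 10.1% and 6.50%.

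The authors also deposited 2 result tables, over all genes and over a top 25 percent of genes, whose columns are, per the file headers, those of DESeq2: a mean count, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. The deposited p-value equalled the upper tail of a chi-square distribution with 1 degree of freedom at the deposited score, to within 3.41e-15, in the 19437 genes of the first table and 5600 of the other that had a p-value, as a likelihood ratio test gives. The direction of the deposited log2 fold change was not given per the file headers. Its sign was opposite to that of the KO over WT change in translational efficiency for 72.1% of 7203 shared genes (Pearson correlation across genes -0.646), so it is taken here, as an inference, as WT over KO.

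Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05), with genotype and batch in the model. Total RNA and RPF libraries were fitted separately, and translational efficiency (RPF relative to total RNA) was tested as the interaction of genotype and molecule in a single model over the 24 libraries, with molecule by batch, which takes the 2 libraries of a culture as independent. CPM (counts scaled to a common library size) were computed with TMM factors, and log2 CPM used a prior count of 2. Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with quality weights, other scalings, filters, gene sets and thresholds, no batch term, single batches, a replicate block, and leaving out each culture in turn or all cultures with an RPF library under 1000000 counts. Tests, alternatives, gene lists and the naming rule were chosen before the data were examined. Leaving out batch 2, batch 3 or the KO6 and WT6 pair, and 2 further checks of the genes near Apobec1, were chosen after seeing the data, and so were the permutation within batches of reads counted for no gene and the tests of explanations that the closing part names as such.

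The 33 fixed lists covered reported APOBEC1 editing targets, APOBEC1 cofactors and deaminases, the neighbours of Apobec1, cytosolic ribosomal proteins, translation initiation and elongation factors, the integrated stress response, endoplasmic reticulum chaperones, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, alternative activation, MHC class I and class II presentation, phagocytic and scavenger receptors, lysosome, NADPH oxidase, cholesterol biosynthesis, LXR targets and lipid handling, cell adhesion and migration, cell cycle, replication-dependent histones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, glycolysis and hypoxia, oxidative stress and iron, and sex-linked genes. They also held markers of macrophages, monocytes, neutrophils, dendritic cells, mast cells, lymphocytes, erythroid cells, and stromal, endothelial and osteoclast cells. Lists with at least 3 tested members were tested against all other genes with camera (preset correlation 0.01, two-sided), and again with an estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance.

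Named genes are Apobec1, called genes over a log2 CPM of 1 with the same sign inside each batch (up to 10 per direction), the 10 smallest-p genes where fewer than 5 were called, per list up to 4 members where at least 1 passed and otherwise up to 2, the editing targets, up to 6 called genes within 10 Mb of Apobec1, and genes picked by an outlier screen. Any gene outside this rule is marked as chosen after its values were seen. Of 23337 gene symbols, 20756 matched the reference gene table of the same assembly by symbol and 2331 by synonym, and 250 did not match; coordinates are those of mm10. No 2 libraries of a group agreed within sampling noise over 60 pairs (lowest chi-square per degree of freedom 1.22). Binomial intervals and floors of 3 counts cover counting error only.

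The procedure was tested on simulated counts with known changes. A 4-fold change was recovered for 100% of simulated genes in each comparison, and a 2-fold change for 80% to 84% in total RNA (10942 genes), 88% in RPF (7208 genes) and 72% to 80% in translational efficiency (7203 genes). A log2 change of 0.5 was recovered for 36% to 52%, 16% to 24% and 4% to 8%, respectively. Of the unchanged genes, 10 of 10701, 12 of 6968 and 7 of 6963 were called. The simulated counts were drawn independently for each gene and library around the batch means. They held no shift of a whole culture and no link between genes or between the libraries of a culture. These rates therefore do not cover data with such structure.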

Results

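Ribosome profiling and total RNA sequencing were compared between macrophages grown from the marrow of 6 WT and 6 Apobec1-deficient cultures, to ask how functional APOBEC1 affects translation. APOBEC1 is a cytidine deaminase that edits C to U in RNA, known for editing apolipoprotein B mRNA in the intestine. Total RNA libraries held 5077478 to 12059361 counts in genes. RPF libraries were shallower and far more uneven, from 29561 counts in WT6 and 90773 in KO6 to 3714912 in WT4. Batch took 71.6% of the variance of total RNA and 35.6% of that of footprints, against 3.81% and 8.11% for genotype after batch. Any grouping of the cultures takes some share, and none was computed for other groupings, so these genotype shares do not show an effect. No difference between genotypes was called in reads counted for no gene: the shares outside features, ambiguous or with several alignments had exact two-sided permutation p-values of 0.333 to 0.635 over the 96 regroupings within batches and 0.197 to 0.879 without regard to batch (6 tests). Counts of Y-linked genes set batch 3 apart, with 0 or 1 counts of Ddx3y, Eif2s3y, Kdm5d and Uty in every total RNA library against at least 155 elsewhere, while Xist, the X-inactivation transcript, had 172 to 386 counts there and 2 to 11 elsewhere.

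The targeted gene was measured first. Apobec1 (chromosome 6, 122577792 to 122603024) had more RNA and fewer footprints in KO than in WT. Total RNA of Apobec1 was 989 ± 270 CPM in KO and 385 ± 64.5 CPM in WT (SD, n = 6 each), a 2.53-fold rise (log2 1.34, SE 0.11, edgeR adjusted p = 1.39e-04), from 4286 to 8754 counts per KO library and 2072 to 5737 per WT library. Footprints of Apobec1 were 8.66 ± 8.42 CPM in KO and 84.2 ± 22.1 CPM in WT and fell by 3.51 on the log2 scale (SE 0.29, edgeR adjusted p = 5.13e-08), from 0 to 22 counts per KO library and 3 to 353 per WT library. The ratio of footprint to RNA CPM ranged from 0.145 to 0.297 in WT and did not exceed 0.0213 in KO, so all 12 cultures stood on the side their labels give. Within batches 1, 2 and 3 the KO minus WT difference was 1.39, 1.68 and 1.05 log2 CPM in total RNA and -1.74, -3.82 and -4.15 in footprints. The counts cover the whole gene, so they do not check whether the deleted part was transcribed, and with 29561 counts in WT6 a level under 101 CPM is below 3 counts there. The rise of Apobec1 RNA missed the threshold within batch 3 alone (log2 1.05, adjusted p = 0.624).

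**Figure D1:**
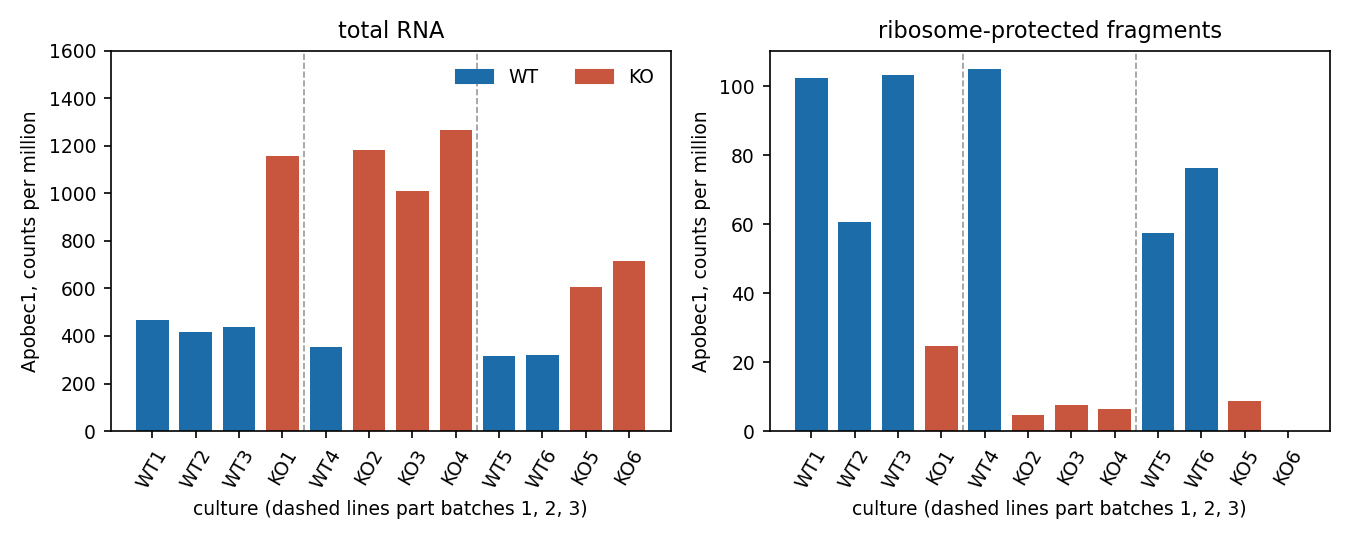
Apobec1 CPM in each culture in total RNA (left) and RPF (right), 1 bar per culture, with dashed lines between batches. KO1 had 24.7 CPM of footprints from 15 counts, and KO6 had 0 counts in a library where 3 counts equal 33.1 CPM.

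Total RNA was compared between KO and WT to ask which transcripts differed without functional APOBEC1. Beside Apobec1, Dppa3 was the other gene of 10942 that passed the test. Dppa3, a maternal-effect gene that guards DNA methylation in the early embryo, fell by 3.35 on the log2 scale (SE 0.39, edgeR adjusted p = 0.00407), from 3.28 ± 0.72 CPM in WT to 0.33 ± 0.25 CPM in KO (SD, n = 6 each). It starts 23.4 kb from the end of Apobec1 (chromosome 6, 122626424 to 122630271) and rested on few reads, 170 counts over the WT and 12 over the KO libraries; it has near-identical processed copies in the mouse genome, so its count is uncertain. Its difference in log2 CPM was -3.22, -1.87 and -3.02 within batches 1, 2 and 3, and its call was lost with KO6 and WT6 left out together (log2 -3.10, adjusted p = 0.102) or batch 3 left out (adjusted p = 0.476). Between Apobec1 and Dppa3 lies Gdf3, a growth factor of the TGF-beta family, which was at log2 1.36 in total RNA (SE 0.39, adjusted p = 0.859) and 1.60 in footprints (SE 0.47, adjusted p = 0.397). DESeq2 called 7 genes and limma voom 5; at an unadjusted p under 0.05, 209 genes were higher and 303 lower in KO. Leaving out KO1 raised the count to 9 and leaving out batch 2 raised it to 8.

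The smallest p-values in total RNA lay mostly on chromosome 6. Of the 10 genes with the smallest p, 7 lay on chromosome 6, which holds 4.89% of tested genes (exact hypergeometric p = 6.83e-08 across genes, which are not independent), and the other 3 on chromosome 11, where genes with an unadjusted p under 0.05 were not enriched (adjusted p = 0.354). On chromosome 6 these were Apobec1, Dppa3, the paraoxonase Pon2 (log2 -0.51), the DNA glycosylase Mbd4 (0.59), the RNA helicase Ddx47 (-0.43), the proton-pump subunit Atp6v1e1 (-0.42) and the lectin Clec2i (0.79). On chromosome 11 they were BC018473, a non-coding RNA (log2 -0.76), 1200014J11Rik, also called Ncbp3 (-0.58), and the myeloid receptor Cd300e (1.02). Besides Apobec1 and Dppa3 none of the 10 passed over all genes (adjusted p from 0.272 to 0.551), but BC018473 passed without WT4 (log2 -0.93, adjusted p = 0.0306) and Pon2 without KO1 (log2 -0.64, adjusted p = 0.0499). Within 10 Mb of Apobec1, Dppa3 was the 1 of 147 tested genes besides Apobec1 that passed, against 0 of 10722 others by edgeR (Fisher's exact p = 0.0135, which is the chance that a single called gene falls there; p = 1.84e-04 with Apobec1, whose place is given by the design). Counting genes with an unadjusted p under 0.05 instead, a measure chosen after seeing the data, gave 16 of 148 (10.8%) against 4.59% elsewhere (Fisher's exact p = 0.00229, and 0.00441 without Apobec1), 9 of them higher and 7 lower in KO. In a 5 Mb window this measure did not pass (8 of 84, Fisher's exact p = 0.0598, and 0.111 without Apobec1), in a 20 Mb window it did (23 of 191, Fisher's exact p = 2.83e-05, and 7.43e-05 without Apobec1), and chromosome 6 as a whole did not (adjusted p = 0.165).

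**Figure D2:**
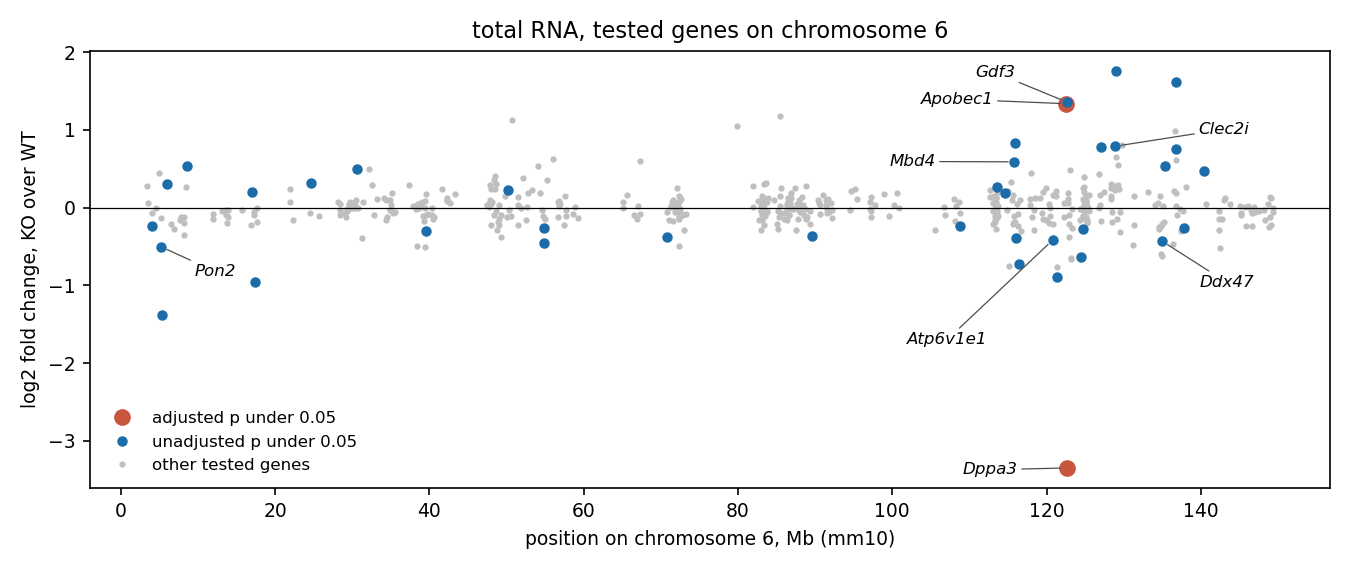
Total RNA log2 fold change, KO over WT, of tested genes along chromosome 6 (position in Mb, mm10). Apobec1 (1.34) and Dppa3 (-3.35) passed over all genes; genes with an unadjusted p under 0.05 are marked separately.

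Among the fixed lists, transcripts of ribosomal proteins, respiration and cholesterol synthesis stood lower in KO total RNA, and interferon-stimulated and cell cycle transcripts higher. Camera called 11 of 29 lists, 3 higher and 8 lower, and none of the 11 held with an estimated correlation (lowest adjusted p = 0.573 with an estimated correlation) or with fry (lowest adjusted p = 0.373). Cytosolic ribosomal protein genes had 77 of 79 members lower (median log2 -0.16, adjusted p = 1.50e-13; adjusted p = 0.573 with an estimated correlation), among them Rps16 (-0.39) and Rpl28 (-0.18). Interferon-stimulated genes had 38 of 45 members higher (median log2 0.16, adjusted p = 4.21e-10; adjusted p = 0.573 with an estimated correlation), led by Ifi44 (0.49, adjusted over the list alone p = 0.0269), Dhx58 (0.22), a sensor of viral RNA, and Oasl2 (0.27). These 2 lists kept their calls whichever single culture was left out. Leaving out batch 3 ended the camera call of the ribosomal proteins (adjusted p = 0.124). Ifi44, the only interferon-stimulated gene to pass over the list alone, with 0 passing over all genes, did not pass in edgeR without KO1 (adjusted p = 0.157 over the list alone), nor without WT3, WT4, WT6, KO2 or KO6 (0.0593, 0.0569, 0.0882, 0.0578 and 0.0950).

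A further 7 lists called in total RNA lost their calls without WT4, the only WT culture of batch 2. Cholesterol biosynthesis genes had 23 of 24 members lower (median log2 -0.36, adjusted p = 1.11e-08, and 0.399 without WT4), such as Mvd (-0.73) and Cyp51 (-0.46), and nuclear-encoded oxidative phosphorylation genes 53 of 54 lower (median -0.15, adjusted p = 1.60e-09, and 0.231 without WT4), such as Cox6c (-0.29). Cell cycle genes had 35 of 43 members higher (median 0.15, adjusted p = 6.10e-06, and 0.345 without WT4), such as the replication helicase subunit Mcm4 (0.35) and Uhrf1 (0.32). Neutrophil and granulocyte precursor markers had 11 of 12 members lower (median -0.45, adjusted p = 5.65e-04, and 0.605 without WT4). Their Mmp9 (-1.19) passed in edgeR adjusted over the list alone (adjusted p = 0.0141, and 0.668 without WT4 or 0.0519 without KO2), with 0 members passing over all genes. Oxidative stress and iron genes (22 of 25 lower, adjusted p = 3.32e-05), glycolysis and hypoxia genes (23 of 29 lower, 6.85e-04) and integrated stress response genes (22 of 29 lower, 0.0176) turned to the other direction without WT4, at 0.406, 0.531 and 0.207; the last list also lost its call without KO1 (0.128) or KO2 (0.101). These calls were lost with an estimated correlation, at an adjusted p = 0.628 with an estimated correlation for glycolysis and hypoxia, 0.670 for the integrated stress response and 0.573 for the other 5 lists. Within batch 2, WT4 stood apart in some markers of another cell type. Its total RNA held 225 CPM of Mmp8, a neutrophil collagenase, 12.7 times the mean of the KO cultures of its batch. It held 3.85 times their S100a8, a calcium-binding protein abundant in neutrophils. It also held 6.98 times their Lcn2, 4.54 times their Mmp9 and 2.34 times their S100a9, but 1.47, 1.31 and 1.44 times their Ngp, Camp and Ltf. The WT cultures of batch 3 averaged more S100a8 than WT4 (141 against 63.5 CPM), and more S100a9, Ngp, Camp, Ltf and Cebpe. They averaged less Mmp8 (27.5 CPM), Mmp9, Lcn2, Csf3r, Cxcr2 and Padi4.

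The last 2 lists called in total RNA were those of cofactors and of LXR targets. APOBEC1 cofactors and deaminases had 9 of 12 members higher, Apobec1 included (adjusted p = 0.00680, and 0.149 without WT4 or 0.0706 without WT5; adjusted p = 0.573 with an estimated correlation), and of the others the RNA editing enzyme Adar was at log2 0.17. LXR targets and lipid handling genes had 16 of 26 members lower (adjusted p = 0.0414; adjusted p = 0.573 with an estimated correlation). Of these, Fabp4, a fatty acid carrier (log2 -0.81), and Acsl3 (-0.28) passed adjusted over the list alone (0.0399 and 0.0416), with 0 passing over all genes by edgeR; both failed without WT4 (0.355 each) and without most other single cultures. The call of the list itself was lost without WT1, WT3, WT6, KO1, KO3 or KO5 (adjusted p from 0.0518 to 0.281). Adjusted over the list alone, Ctsk, an osteoclast protease (log2 -0.91, 0.0440), also passed, and it did not without WT4 (0.386) nor without WT2, WT3, WT5, KO2, KO3, KO5 or KO6 (0.0505 to 0.131).

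No call was made in total RNA for the remaining lists. Their adjusted camera p was 0.406 for the editing targets, 0.379 for the neighbours of Apobec1 (1 of 45 called, Dppa3), 0.0768 for initiation and elongation factors, 0.833 for endoplasmic reticulum chaperones, 0.567 for NF-kB targets, 0.833 for alternative activation, 0.372 for MHC class II, 0.947 for MHC class I, 0.827 for phagocytic receptors, 0.294 for lysosome, 0.131 for NADPH oxidase, 0.406 for adhesion, 0.827 for histones, 0.833 for sex-linked genes, 0.827 for macrophage identity, 0.494 for monocyte, 0.537 for dendritic cell and 0.528 for stromal, endothelial and osteoclast markers. Mast cell, lymphocyte and erythroid markers had 1 tested member each (Kit at log2 0.22, Cd79b at -0.36 and Pf4 at 0.09), and the mitochondrially encoded list had 0 members among the counted symbols. Median, mean and test differed in sign for NF-kB targets, alternative activation, MHC class I, adhesion, histones, macrophage identity and the stromal list, none of them called.

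**Figure D3:**
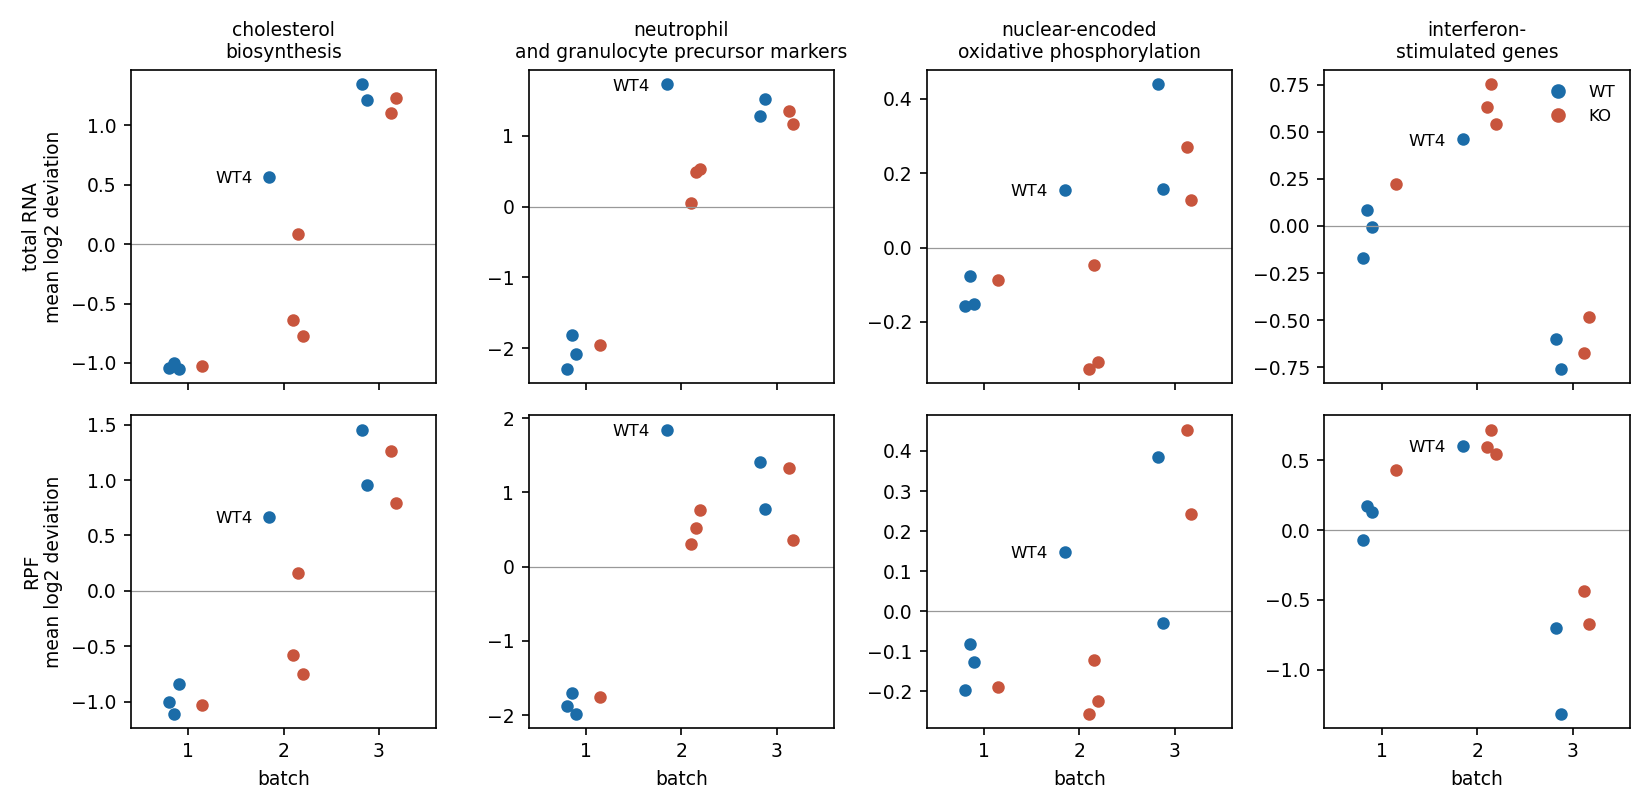
Mean log2 deviation from the mean of all cultures for the members of 4 lists, per culture and batch, in total RNA (top) and RPF (bottom). In batch 2 the only WT culture, WT4, lies above the 3 KO cultures for cholesterol biosynthesis, neutrophil and oxidative phosphorylation genes.

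Footprints were compared to ask which coding sequences were occupied differently. Of 7208 genes, 6 passed the test and all were lower in KO. After Apobec1 these were Ifitm6, an interferon-induced transmembrane protein family member (log2 -1.65, SE 0.24, edgeR adjusted p = 2.83e-04), and S100a8 (-1.28, SE 0.23, adjusted p = 0.00838). Dmxl2, a regulator of the vacuolar proton pump chosen after its values were seen (-1.46, SE 0.28, adjusted p = 0.0131), Fabp4 (-1.23, SE 0.24, adjusted p = 0.0148) and the gelatinase Mmp9 (2.84-fold lower, SE 0.31 in log2, adjusted p = 0.0335) did not keep the same sign inside every batch. Their differences in log2 CPM within batches 1, 2 and 3 were -0.12, -1.78 and 2.23 for Dmxl2, -0.56, -1.52 and 1.68 for Fabp4, and -0.86, -1.65 and 1.69 for Mmp9. In batch 3 WT6 had 0 counts of these 3 genes in a library where 3 counts equal 101 CPM, so the positive values rest on a level below what it resolves. The differences were -0.78, -1.81 and -1.01 for Ifitm6 and -1.31, -1.76 and -0.28 for S100a8. For S100a8 the batch 1 value rests on KO1, the only KO culture of that batch. KO1 stood at the log2 CPM that 0 counts give (0.62), in a library where 3 counts equal 4.64 CPM. At an unadjusted p under 0.05, 284 genes were higher and 330 lower. DESeq2 called 3 genes and limma voom 1.

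Without WT4, Apobec1 was the only gene called in footprints. Ifitm6 was then at log2 -0.90 (adjusted p = 0.950), S100a8 at -0.31 (0.987) and Fabp4 at -0.55 (0.974), and Dmxl2 and Mmp9 fell under the count filter. The count of called genes also moved by more than 1.5 times without KO2 (2 genes), KO4 (3), KO1 (269), WT1 (23), KO5 (22), WT6 (17), WT5 (15) or WT2 (13). S100a8 lost its call without KO2 (adjusted p = 0.125), Fabp4 without WT3, KO2 or KO4 (0.0612, 0.195 and 0.0827), and Mmp9 without KO6 (0.0502).

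Lipid synthesis and neutrophil genes were the footprint lists with the largest shifts. Camera called 5 of 28 lists, 2 higher and 3 lower in KO. Cholesterol biosynthesis genes were lower in 20 of 20 members (median log2 -0.75, adjusted p = 7.71e-06; adjusted p = 0.910 with an estimated correlation), and 10 passed adjusted over the list alone against 0 over all genes by edgeR, among them Nsdhl (-1.08), Cyp51 (-0.93), Sc4mol (-0.76) and Lss (-0.89). Neutrophil markers were lower in 8 of 8 members (median -0.65, adjusted p = 0.00608; adjusted p = 0.910 with an estimated correlation), with 2 passing over all genes and 4 adjusted over the list alone: S100a8, Mmp9, Mmp8 (-3.05) and S100a9 (-0.84). Oxidative phosphorylation genes were lower in 44 of 54 members (median -0.17, adjusted p = 0.00580; adjusted p = 0.939 with an estimated correlation), such as Cox7b (-0.63) and Ndufb5 (-0.61). Cell cycle genes were higher in 38 of 41 members (median 0.26, adjusted p = 0.00297; adjusted p = 0.939 with an estimated correlation), such as Mcm6 (0.48) and Cenpf (0.63). Interferon-stimulated genes were higher in 33 of 41 members (median 0.16, adjusted p = 0.00608; adjusted p = 0.939 with an estimated correlation), such as Ifi204 (0.46) and Oasl1 (0.58).

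Without WT4 the first 4 of these footprint lists lost their calls. The adjusted p was then 0.155 for cholesterol biosynthesis and 0.481 for neutrophil, oxidative phosphorylation and cell cycle genes, and none of the named members of the first 2 lists passed over the list alone: Nsdhl was at -0.50, Cyp51 at -0.48, Sc4mol at -0.31, Lss at -0.27, S100a9 at -0.23 and Mmp8 on the other side of 0, at 0.96. Lss also failed without KO2 (0.0570). The cell cycle call was also lost without WT5 (0.205). The interferon-stimulated call stood without WT4 (0.0111) but was lost without WT5 (0.152) or KO1 (0.620).

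Members of footprint lists that were not called as a whole also passed adjusted over the list alone. These were the iron exporter Slc40a1 (log2 1.25), the metallothionein Mt2 (-2.16) and Prdx6 (-1.11) among oxidative stress and iron genes, and Fcgr2b (-0.90), Lrp1 (0.42) and Scarb1 (-0.48) among phagocytic receptors. They also included the integrins Itga9 (1.22) and Itgav (0.52), Clec10a (0.74), Cd83 (1.09), Clec4b1 (1.51), Gpr141 (-0.84), Ctsk (-1.76), Ero1l (-0.78), the lactate carrier Slc16a3 (-0.51), Gapdh (-0.41), Acaca (-0.69) and Scd2 (-2.15). By edgeR 0 of these 18 passed over all genes. Without WT4 the call was lost for Slc40a1 (0.262), Mt2 (0.849), Fcgr2b (0.820), Lrp1 (0.262), Scarb1 (0.262), Itgav (0.355), Clec10a (0.373), Cd83 (0.922), Clec4b1 (0.506), Gpr141 (0.457), Ero1l (0.963), Slc16a3 (0.826), Gapdh (0.579), Acaca (0.698) and Scd2 (0.655), and Prdx6 turned to log2 0.05. Scarb1 (-0.52) and Lrp1 (0.36) kept about their size then, and calls were also lost without other single cultures. This held for Lrp1 without WT1, WT2, WT5, WT6, KO2, KO4, KO5 or KO6 and Scarb1 without the same except WT6 (0.0564 to 0.354 for both), for Gpr141 without WT2, WT3, WT5, WT6, KO2, KO4 or KO5 (0.0547 to 0.142), and for Scd2 without WT1, WT2, WT3, KO2, KO3, KO4 or KO5 (0.0539 to 0.121). It also held for Prdx6 without WT2, WT5, KO2, KO3 or KO6 (from 0.0542), Gapdh without WT2, WT5, KO2, KO4 or KO5 (0.0535 to 0.0826), Slc16a3 without WT2, KO2 or KO4 (0.0634 to 0.0826), Ero1l, Fcgr2b and Itgav without KO2 or KO4 (0.0524 to 0.0826), Acaca without KO2 (0.0829), Cd83 without WT3 (0.0637) and Ctsk without KO4 (0.0636).

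No call was made in footprints for the remaining lists. Their adjusted camera p was 0.823 for the editing targets, 0.620 for cofactors and deaminases, 0.866 for the neighbours of Apobec1, 0.174 for ribosomal proteins (59 of 77 lower), 0.240 for initiation and elongation factors, 0.886 for the integrated stress response, 0.619 for endoplasmic reticulum chaperones, 0.745 for NF-kB targets, 0.985 for alternative activation and for lysosome, 0.430 for MHC class II, 0.450 for MHC class I, 0.566 for phagocytic receptors, 0.337 for NADPH oxidase, 0.438 for LXR targets and for histones, 0.133 for adhesion, 0.174 for glycolysis and hypoxia, 0.170 for oxidative stress and iron, 0.958 for sex-linked genes, 0.215 for macrophage identity, 0.866 for monocyte markers and 0.515 for the stromal list. Median, mean and test differed in sign for editing targets, cofactors, neighbours, alternative activation, MHC class II, histones, sex-linked genes and the stromal list. Dendritic, mast cell, lymphocyte and erythroid markers had fewer than 3 tested members.

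Fold changes in footprints followed those in total RNA across genes. Over 7203 genes the Pearson correlation was 0.605 (Spearman 0.503, covariance 0.0280) and 67.4% had the same sign, so that S100a8, Fabp4 and Mmp9 stood low in both, while Apobec1 lay on opposite sides. The correlation was 0.640 over 4457 genes with more reads and 0.628 without Apobec1. Without WT4 it was 0.151. Both fold changes come from the same cultures, so a correlation also arises without the real grouping. Its median over the other regroupings within batches was 0.396, and 13 of 96, the real one included, were as large.

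**Figure D4:**
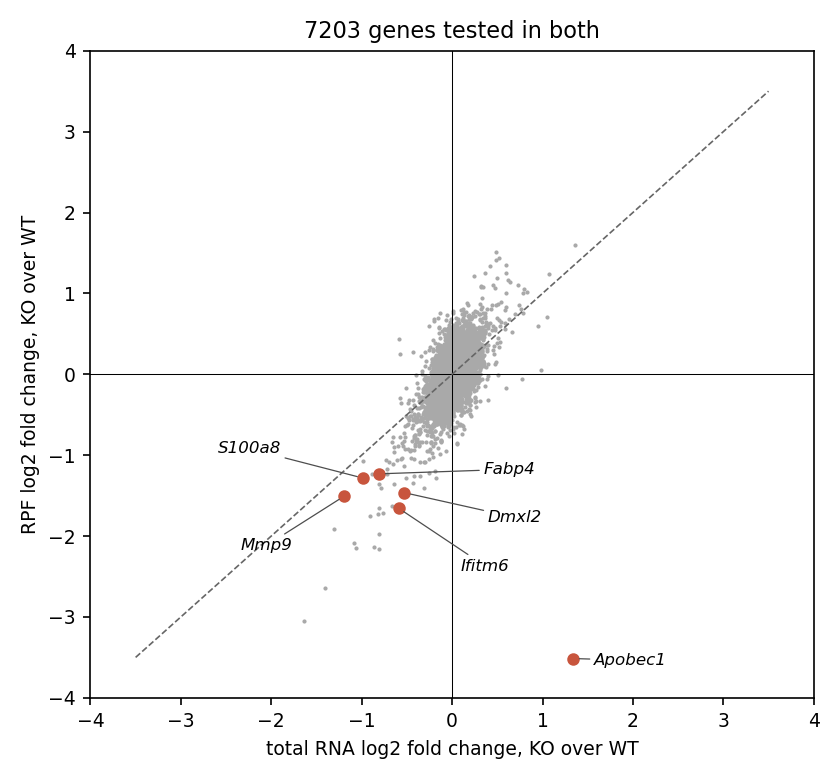
Log2 fold change, KO over WT, in footprints against total RNA for 7203 genes, with the 6 genes called in footprints marked and a dashed line where both are equal. Apobec1 is the marked gene with higher RNA (1.34) and lower footprints (-3.51).

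Translational efficiency was tested to ask whether ribosome occupancy changed beyond RNA level. Apobec1 was the only gene of 7203 that passed. Its efficiency fell by 4.89 on the log2 scale (SE 0.32, 29.7-fold, edgeR adjusted p = 1.41e-10), with a ratio of footprint to RNA CPM of 0.220 ± 0.052 in WT and 0.00871 ± 0.00785 in KO (SD, n = 6 each) and differences of -3.13, -5.52 and -5.19 within batches 1, 2 and 3. Among the other genes with the smallest p, Commd8 was at log2 0.85, Ddx47 at 0.69, Ifitm6 at -1.11, Jmjd8 at -0.92, 1200014J11Rik at 0.81, the aldo-keto reductase Akr1c13 at -1.14, the splicing factor Rbm17 at 0.72 and the kinase Jak3 at -0.77, each with an adjusted p = 1.00. The model takes the 2 libraries of a culture as independent; pairing them kept the Apobec1 call as a block (log2 -5.36) and ended it as a log2 ratio per culture (limma, log2 -4.67, adjusted p = 0.173). At an unadjusted p under 0.05, 86 genes were higher and 95 lower. The authors' deposited table over all genes also held 1 gene with an adjusted p under 0.05, Apobec1 (log2 4.88, SE 0.34, adjusted p = 7.76e-43, taken as WT over KO); their top 25 percent table held Apobec1 (4.90) and, under 0.1, 1200014J11Rik (-1.07, adjusted p = 0.0803).

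No fixed list was called in translational efficiency. Camera called 0 of 28 lists (4 at an unadjusted p under 0.05: cofactors and deaminases, which contain Apobec1, initiation and elongation factors, cholesterol biosynthesis and macrophage identity), and the estimated correlation and fry also called 0 (lowest 0.981 and 0.893). Adjusted camera p was 0.347 for cholesterol biosynthesis and macrophage identity, 0.374 for ribosomal proteins, 0.783 for MHC class I, 0.882 for the stromal list and 0.830 to 0.986 for the others, except for initiation and elongation factors and for cofactors, which had the 2 lowest. In cholesterol biosynthesis 19 of 20 members lay below 0 (median -0.39), and 2 of them had an unadjusted p under 0.05. Median, mean and test differed in sign for editing targets, neighbours, the integrated stress response, interferon-stimulated genes, alternative activation, MHC class II, lysosome, NADPH oxidase, histones, glycolysis, oxidative stress, monocyte and stromal lists.

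Transcripts reported as APOBEC1 editing targets were examined as a group, since editing of their 3' untranslated regions could alter RNA level or translation. None was called at any level, with 25 tested in total RNA and 24 each in footprints and efficiency. Log2 fold changes ranged from -0.32 (Rnf128) to 0.44 (Clic5) in total RNA, from -0.50 (Rnf128) to 0.42 (Reps2) in footprints and from -0.20 (Rnf128) to 0.26 (Mcmbp) in efficiency. The 95% interval lay within a 2-fold change either way for 24 members at each level. The lowest unadjusted edgeR p was 0.0183 (Cnih), 0.00962 (the scavenger receptor Cd36) and 0.145 (Mcmbp), and the adjusted camera p was 0.406, 0.823 and 0.986. Editing itself was not analysed here.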

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

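The tests of a mislabelled library, of transcription from the undeleted part of Apobec1, of poorer alignment, of neutrophils in WT4 and of chromosome 6 among the smallest p-values, and the rule that left DNA around the deletion open, were chosen only after the result was seen.

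Single cultures stood far from the 5 others of their genotype for several named genes, measured as the gap to the nearest culture over the whole range of the 6. In total RNA, WT4 was highest for the transcription factor Cebpb (0.689) and for Rpl28 (0.784), and WT5 lowest for Celf2 (0.726). In WT footprints, WT4 was highest for Ifitm6 (0.667) and Ndufb5 (0.655), and WT6 lowest for Clec10a (0.725), Fabp4 (0.770), Mmp9 (0.681) and Oasl1 (0.699). In KO footprints, KO1 was lowest for S100a8 (0.641), S100a9 (0.654) and Ndufb5 (0.700), KO6 for Clec4b1 (0.659) and KO3 for Gdf3 (0.767). For the footprint to RNA ratio, WT6 was lowest for 1200014J11Rik (0.710), Akr1c13 (0.698) and Rbm17 (0.907), and KO6 for Akr1c13 (0.842) and Jmjd8 (0.843). These were 19 of 180 groups (10.6%), where chance picks about 1 in 20 groups, or 9. WT6 and KO6, the shallowest RPF libraries, made up 7 and 3 of them, WT4 made up 4 and KO1 made up 3. The screen did not adjust for batch, and its chance rate assumes no batch differences. WT4 and KO1, each alone for its genotype in a batch, may therefore stand out through their batch. The batch 1 WT cultures also had little S100a8 and S100a9 in total RNA (0.78 and 0.63 CPM).

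Apobec1 differed between molecules: its KO effect was 1.34 in total RNA and -3.51 in footprints, and the difference was tested as an interaction (log2 -4.89, edgeR adjusted p = 1.41e-10). A library mislabelled for genotype was argued against, since the lowest WT ratio of footprint to RNA was 6.82 times the highest KO ratio. The ratio cannot show a swap of libraries within a genotype. Footprint libraries correlated best with the RNA library of their own culture in 5 of 12 cultures, WT4 among them. Few footprint counts were argued against only in part. The cultures with at least 1000000 footprint counts (WT1, KO2, KO4 and WT4) gave a log2 fold change of -4.27. With batch in the model, that value sets WT4 alone against KO2 and KO4. Transcription from the undeleted part of the gene may underlie the 2.53-fold RNA rise, but 1 count per gene does not show where reads lie, so this could not be told apart from a change in RNA stability or transcription. For translational efficiency, 1 of 100 splits of the cultures, the real split itself, gave as many genes (real value 1, highest other split 0). That gene is Apobec1, disrupted by design, so this comparison does not test chance for any other gene. Among the 96 splits within batches the highest other also called 1.

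Genes near Apobec1 differed in total RNA more often than genes elsewhere: with an unadjusted p under 0.05, 10.8% did so within 10 Mb against 4.59%. Of the 10 smallest p-values 7 lay on chromosome 6, but Pon2 (start 5264620) and Ddx47 (start 135011612) lay outside that window. The first 10 Mb of chromosome 6, far from Apobec1, held 5 of 19 genes with such a p (26.3%, one-sided Fisher's exact adjusted p = 0.179). The 10 Mb stretch holding Apobec1 had 10 of 89 (11.2%, adjusted p = 0.568). With Apobec1 left out, 1 of 96 splits within batches, the real split, placed as many of the 10 smallest on any 1 chromosome (real value 6, highest other split 4). So did 2 of 100 splits regardless of batch (highest other split 6). This measure was chosen after the pattern was noticed, so it does not exclude chance. Poorer alignment of reads with strain variants would lower most of the differing genes near Apobec1 in KO. As their single cause it was argued against, since 56.2% were higher (9 of 16, 95% interval 29.9% to 80.2%). Examples were Mbd4, Ccnd2 and Plxnd1, the last 2 chosen after their values were seen. Without Apobec1, 8 of 15 were higher. Poorer alignment was not excluded for the genes that were lower. DNA of another strain kept around the deletion may account for the differences within 10 Mb of Apobec1. Yet 7 of 96 splits within batches had a near over elsewhere ratio as large (real value 2.36, highest other split 3.04). Chance was not excluded, and the bound written before the splits were run (the real ratio exceeded in over 5% of them, as it was in 6 of 96) counted against the explanation; it was set aside only after these values were seen, and the explanation left open, since a share just over 5% does not show that enrichment is absent and the median of the other splits was lower (1.16). Such DNA elsewhere, as for the chromosome 11 genes BC018473 and Cd300e, also stays open: the lowest adjusted p of a 10 Mb window outside chromosome 6 was 0.179, but the window of Apobec1 itself did not pass (0.568).

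Footprint differences that rest on WT4, such as those of S100a8, Fabp4 and the cholesterol biosynthesis genes, were the third pattern. The depth of the WT4 library was argued against, since 99.2% of 479 genes called within batch 2 had the same sign in total RNA of that batch, where WT4 had an ordinary depth. Genotype as a shared cause was argued against, since 43.0% had the same sign in total RNA of batches 1 and 3, against 50.6% of all genes. Neutrophils in WT4 stay open: its S100a8 fold over the WT cultures of batch 3 was 0.0549 of its Mmp8 fold, but those cultures themselves held more S100a8 (141 against 63.5 CPM), and over the KO cultures of its own batch S100a8 and Mmp8 were 3.85 and 12.7 times higher, Lcn2, Mmp9, S100a9 and Cebpe 2.02 to 6.98 times, and Ngp, Camp, Ltf, Csf3r, Cxcr2 and Padi4 1.15 to 1.69 times. A different state of the WT4 macrophages stays open as an untested explanation.

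The other counts were also set against splits of the cultures, and for these chance could not be excluded. In total RNA 5 of 100 splits called as many genes (real value 2, highest other split 6), and in footprints 15 of 100 (real value 6, highest other split 342). The highest split put KO1, WT1, WT2, WT3, WT4 and WT6 together; it held all of batch 1 on 1 side and, with batch in the model, set WT4 alone against KO2, KO3 and KO4. Within batches 18 of 96 splits called as many footprint genes, and the highest other (112) also set WT4 alone against these 3, which points to a structure of the samples. Lists past the threshold were as many in 22 of 96 splits within batches for total RNA (real value 11, highest other split 18) and in 17 of 96 for footprints (real value 5, highest other split 9). The correlation of footprint with total RNA fold changes was as large in 13 of 96 (real value 0.605, highest other split 0.762).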

How the results depend on the processing

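Leaving out batch 2, batch 3 or the KO6 and WT6 pair was chosen only after the result was seen. The answers to the comparisons held in 206 of 271 alternative values (33 weaker, 29 stronger, 3 moved, 0 reversed), and named genes and lists in 2148 of 2668 (405 weaker, 59 stronger, 37 moved, 19 reversed). Much of the first share restates the targeted gene. Apobec1 itself held in 27 values for total RNA, 27 for footprints and 28 for efficiency. The efficiency calls (27 held) rest mainly on Apobec1, and most tests of genes near Apobec1 (19 held) kept it in the window. The number of genes called in footprints held in 6 values (13 stronger, 10 weaker). Unless a smaller set of genes or cultures is named, the cause was not tested. Apobec1 footprints stayed called under the 27 alternatives in which the gene was tested (log2 -4.27 to -1.93). With at least 10 counts in every library Apobec1 was not tested in footprints, since KO6 had 0 counts of it. Genes called in total RNA (2) became 7 with DESeq2 (2 shared), 5 with voom, 10 with no filter, 1 with at least 10 counts in every library, 1 among the top 25 percent genes, 42, 285 and 0 within batches 1, 2 and 3, 2740 in deep cultures only, 1 without the KO6 and WT6 pair, 8 without batch 2, 1 without batch 3 and 2 to 9 with single cultures left out. Genes called in footprints (6) became 3 with DESeq2, 1 with voom, 12 with upper quartile factors, 159 with no filter, 0 of 511 with at least 10 counts in every library, 16 at an adjusted p under 0.1, 1 with no batch term, 15, 506 and 2 within batches, 1413 in deep cultures, 2 without batch 2, 19 without batch 3 and 1 (WT4) to 269 (KO1) with single cultures left out. In batches 1 and 2 the lone KO or WT culture is assumed to vary like the other group. The same holds for the deep cultures (WT1, KO2, KO4 and WT4), where the batch term leaves WT4 alone against KO2 and KO4. Their counts therefore do not show a gain from depth. Efficiency calls (1) became 0 of 510 with at least 10 counts in every library, 0 within batch 3 and 2 in deep cultures. Apobec1 RNA was at 1.05 within batch 3 (adjusted p = 0.624). The correlation (0.605) was 0.289 with no batch term, 0.203 without batch 2 and 0.151 to 0.722 with single cultures left out. Lists called in total RNA (11) became 0 with an estimated correlation, 0 with fry, 5 without batch 2 and 5 to 12 with single cultures left out. Lists called in footprints (5) became 0 and 0 likewise, 10 in deep cultures, 3 without batch 2, 9 without batch 3 and 2 to 7 with single cultures left out. Lists called in efficiency (0) became 2 in deep cultures, 1 without batch 2, 1 without batch 3 and 0 to 1 with single cultures left out. The numbers of WT and KO cultures pair nothing in the labels; as a replicate block they gave 0 genes in total RNA, 3 in footprints, 7 lists in total RNA and 1 in footprints, with Apobec1 at 1.30 in total RNA (adjusted p = 0.0620). For efficiency, pairing the RPF and RNA library of each culture called 1 gene as a block (Apobec1 at -5.36) and 0 as a log2 ratio (Apobec1 at -4.67, adjusted p = 0.173). Footprint and RNA libraries of a culture correlated above 0.1 in 8 of 12 pairs and best with each other in 5 of 12. Direction reversed in footprints for S100a9 (0.068) and Lrp1 (-0.12) with no batch term, for Lss (0.33), Mt2 (0.0478), Prdx6 (0.23), Lrp1 (-0.068) and Ero1l (0.0432) within batch 1, and for Prdx6 without batch 2 (0.046). With single cultures left out Mmp8 ran from -3.46 (KO1) to 0.96 (WT4) and Prdx6 from -1.75 (KO1) to 0.0508 (WT4). It reversed for neutrophil markers with no batch term (adjusted p = 0.448 in total RNA, 0.975 in footprints), interferon-stimulated footprints in deep cultures (0.942), and in total RNA for the integrated stress response (0.222 without batch 2; 1.47e-04 to 0.207, the latter without WT4, with single cultures left out), glycolysis and hypoxia (likewise 0.435; 7.10e-05 to 0.531) and oxidative stress and iron (0.357; 1.75e-06 to 0.406). With 29561 footprint counts in WT6, levels under 101 CPM (3 counts) were not resolved there.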

Other observations

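All comparisons in this part, and the genes named in it, were chosen only after the result was seen.

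Transcripts of cholesterol biosynthesis stood higher in total RNA of batch 3 than in that of batch 1. With genotype in the model, edgeR called 4955 of 10942 genes (2519 higher, 2436 lower in batch 3). All 24 cholesterol biosynthesis genes were called higher (median log2 2.38, camera adjusted p = 3.54e-15; adjusted p = 0.182 with an estimated correlation), including Cyp51 (3.00, from 26.5 to 209 CPM in WT), Hsd17b7 (3.03) and Insig1 (2.55), genes that SREBP turns on when cells lack sterols. Against batch 2, 20 of 24 were higher (median 1.44; adjusted p = 0.364 with an estimated correlation). Batch 2 itself lay above batch 1, with 21 of 24 higher (median 1.06, camera adjusted p = 0.453 with an estimated correlation). Among LXR targets, Apoe (-5.07, 1733 to 54.6 CPM) and Abca1 (-3.71, 817 to 68.4 CPM) were lower, while the list had 9 members higher and 9 lower (camera adjusted p = 0.801). Cell cycle genes (34 of 43 higher, median 0.85; adjusted p = 0.241 with an estimated correlation), such as Ccna2 (49.3 to 140 CPM) and Birc5 (1.61), and replication-dependent histones (24 of 25 higher, median 1.67; adjusted p = 0.182 with an estimated correlation) were also higher, and the integrated stress response had 18 of 29 higher (adjusted p = 0.388 with an estimated correlation), with Atf4 at 1.09 and Asns at 1.68.

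Mature macrophage genes stood lower in batch 3, and neutrophil and monocyte markers stood higher than in batch 1, with neither list called against batch 2. Macrophage identity genes were lower in 16 of 21 (median log2 -1.16; adjusted p = 0.128 with an estimated correlation), such as the complement genes C1qc (-3.78) and C1qb (-3.72), as were the receptors Mertk (-3.26), Stab1 (-2.68) and Mrc1 (-2.25). Interferon-stimulated genes were lower in 32 of 45 (median -0.58; adjusted p = 0.182 with an estimated correlation), such as Ifi44 (-2.35), and in 42 of 45 against batch 2 (adjusted p = 0.103 with an estimated correlation). Neutrophil and granulocyte precursor markers were higher in 8 of 12 (median 4.51; adjusted p = 0.241 with an estimated correlation), with S100a9 going from 0.63 to 219 CPM and Ltf at 8.71, and monocyte markers had 7 of 13 higher and 3 lower (camera adjusted p = 0.0490; adjusted p = 0.356 with an estimated correlation), such as Chi3l3 (7.99) and Ly6c2 (6.97). Against batch 2, neutrophil markers were 6 higher and 3 lower (camera adjusted p = 0.329) and monocyte markers 5 higher and 5 lower (median -0.82), while batch 2 itself lay above batch 1 in both (medians 4.87 and 2.22; adjusted p = 0.190 and 0.177 with an estimated correlation). Batch 3 was also the batch with Xist (172 to 386 counts) and with 0 or 1 counts of Ddx3y and Uty, so for batch 3 sex and batch cannot be separated, and no explanation was tested. Batches 1 and 2 both had Y-linked counts and 2 to 11 counts of Xist. Batch 2 still lay above batch 1 in cholesterol biosynthesis (21 of 24 higher) and histones (16 of 25 higher, 1 lower). Macrophage identity genes did not fall there (6 of 21 higher, 1 lower).

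Ribosomal protein mRNAs carried few footprints for their RNA level in WT cultures. Over WT1 to WT4 their median log2 footprint to RNA ratio was -1.21 against 0.05 for 7203 genes, and 3 of 77 lay above that median. Among the lists on the other side were MHC class II genes (1.43), neutrophil markers (1.31), alternative activation (0.93), histones (0.81), adhesion (0.72) and lysosome genes (0.68). The neutrophil value is uncertain. In total RNA of the batch 1 WT cultures some of these markers were near 0, such as S100a8 (0.78 CPM) and S100a9 (0.63 CPM). Others were not, such as Csf3r (42.1 CPM). Whether the RNA and footprint counts cover the same regions of a gene was not given in the sources used here, and ribosomal protein genes have near-identical processed copies, so these levels are uncertain.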
